A study of Mus musculus with 17 samples.

How the data were processed

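RNA sequencing of mouse cells was used from 17 libraries, 1 for each combination of genotype and stage. The 3 genotypes were wild type (WT), miR-203 knockout (KO) and miR-203 knock-in (KI), all carrying a cassette that expresses Pou5f1, Sox2, Klf4 and Myc (OSKM) when doxycycline is given. By the labels doxycycline also induces miR-203 in KI cells. The 6 stages were embryonic fibroblasts (MEF), days 0, 4, 6 and 7 of reprogramming, and induced pluripotent stem cells (iPSC), the last in WT and KO only. Libraries were stranded and made from polyadenylated RNA. Per the submitters' processing notes the tools were FastQC, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.16 and Cufflinks 2.2.1 with the builds GRCm38 and mm10. The deposited values are FPKM, fragments scaled to transcript length and mapped reads, as computed by the authors, with 1 value per gene and library. The annotation version and any scaling between libraries are not given in the sources used here.

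The table held 38756 lines. The 41 lines that repeated 1 of 19 gene identifiers were summed, which left 38734 genes, of which 12764 were at 0 in every library. Of the identifiers, 37428 (96.6%) were matched to GENCODE M21, which gave positions and the annotated 3′ untranslated regions. The read depth per library is not given in the sources used here, so no interval for counting error was computed. The sum of FPKM ran from 510501 to 690770 per library, and the most frequent ratio of the values of weakly expressed genes placed relative depths between 0.90 and 1.02 of the WT MEF library. That peak was broad: only 4.5% to 14.4% of the ratios lay within 0.05 (log2) of it.

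Values were analysed as log2 of FPKM plus a pseudocount of 1, for genes with a mean FPKM of at least 1 over the libraries of a fit. That left 14240 genes over 17 libraries and 13837 genes over the 15 libraries before iPSC. Differences were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a variance trend, 2-sided), and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Stage comparisons used all 17 libraries with stage and genotype as terms, so the 3 genotypes served as the separate samples of a stage. Genotype comparisons used 15 libraries with the same terms. A further fit asked whether the difference from WT changed between the early stages (MEF, day 0) and the late stages (days 4, 6 and 7). No combination of genotype and stage had a second library, so the spread in all these fits is the variation of genotype effects between stages, not the variation between cultures or embryos. A group of 5 libraries of 1 genotype holds different stages and is not a set of replicates, so no rule for samples far from their replicates was applied.

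Pairs of single libraries at 1 stage were compared without a test. Genes were counted at a difference of at least 1 (log2) with an FPKM of at least 5 in at least 1 of the libraries. The median difference of a gene list was placed among 10000 random lists matched on mean expression.

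The gene lists, 28 in number, were fixed before the data were examined, and the list of sex-linked markers was used for values only. An alias for 1 gene (Emr1 for Adgre1) was added to the macrophage list afterwards. The 25 other lists with at least 3 members above the filter were tested with camera of limma at a preset correlation of 0.01 and, as an alternative, with an estimated correlation. Adjusted p values cover all lists and comparisons of the stage family or of the genotype family. The lists reported are those for the pluripotency network, the reprogramming factors, fibroblast and mesenchymal genes, smooth muscle and TGF-beta response, epithelial genes, keratinocyte genes, cell cycle, interferon response, inflammatory genes, imprinted genes, HOX genes, glycolysis, DNA methylation, published miR-203 targets, cytosolic ribosome, oxidative phosphorylation, trophoblast, endothelial, neural, and chondrocyte and bone markers, primed and early germ layer genes, extraembryonic endoderm, p53 response and macrophage markers.

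Sites for miR-203-3p were sought in the longest annotated 3′ untranslated region of each gene, as the 7-base match CATTTCA to bases 2 to 8 of the microRNA. Of 11931 genes searched, 2048 had a site. The difference between genes with and without a site was computed after subtracting the median of genes in the same bin of expression and untranslated region length. It was set against 209 control 7-mers of the same base composition and against 10000 random gene lists matched in the same way. The resemblance of the KO and KI differences, which share the WT libraries, was set against 100 simulations with unchanged groups.

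Named genes follow a rule fixed before the data were examined: the 10 largest changes in each direction among called genes with the same sign in every matched pair of libraries, and for pairs of single libraries the 10 largest differences each way. Predicted genes, pseudogenes and short RNA classes were counted but not named by it. Members of the gene lists, Mir203 and the genes within 1 Mb of it may also be named. The short RNA genes that passed the rule under other names are not discussed singly, because FPKM of very short genes is unstable. For genes named in KO or KI against WT, the share of their annotated transcript sequence (in stretches of 31 bases) that other genes also hold was computed, a step chosen after the data were seen. A further gene that passed the rule is not reported here.

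The procedures were tested on simulated data with 100 genes changed by 1 and 100 by 2 (log2). Of these, limma recovered 24% and 83% for day 7 against MEF, 53% and 88% for KO against WT, 57% and 93% for KI against WT, and 9% and 65% for KO in the comparison of late with early stages. Alternatives set before the data were examined covered the pseudocount, the filter, scaling between libraries, the variance trend, the model terms, leaving out each genotype or stage, the list test and the site type. Leaving out the late KI libraries, the WT libraries with low Y-linked RNA, or MEF and day 4 was chosen after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.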

Results

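RNA abundance was measured in mouse cells on the way from embryonic fibroblasts to induced pluripotent stem cells, in WT, KO and KI cells for the microRNA gene Mir203. Each of the 17 libraries stands for 1 genotype at 1 stage: 3 libraries each at the MEF stage and at days 0, 4, 6 and 7, and 2 at the iPSC stage. No group was replicated, so values of single libraries carry no error. The sum of FPKM was lowest in the KI library of day 7 (510501) and highest in the KO library of iPSC (690770). Between 12330 and 13626 genes reached an FPKM of 1 in a library.

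Mir203 (ENSMUSG00000065574, GRCm38 chromosome 12, 112130880 to 112130955) was listed at 0 in every WT and KO library. In the KI libraries its FPKM was 569 in MEF and 185 at day 0, and it stood at 7903, 5863 and 5470 at days 4, 6 and 7. The gene is a hairpin of 76 bases, so its FPKM is unstable, and a value of 0 in WT leaves the deletion in KO unchecked. The libraries were made from polyadenylated RNA, so these values do not measure the mature microRNA, and 0 does not show its absence. Of the 57 annotated genes within 1 Mb of Mir203, Pld4, which encodes an exonuclease of phagocytic cells, had an FPKM of 18.1, 30.8 and 32.9 in WT at days 4, 6 and 7. At these days Pld4 was at 7.31, 3.41 and 3.15 in KI and at 0.202 or less in KO. The macrophage genes Lyz2 and C1qa, which do not lie within 1 Mb of Mir203, had the same order of genotypes at day 7. The Pld4 values therefore do not show a local effect of the deletion.

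The reprogramming factors separated the genotypes after day 0. Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772), a core regulator of pluripotency, reached an FPKM of 266 in WT and 255 in KO at day 4 but 0.851 in KI. At day 7 it was at 85.3 in WT, 954 in KO and 0.675 in KI, and in iPSC at 1362 in WT and 1165 in KO. Sox2, its partner, was at 19 in WT, 29.1 in KO and 0.167 in KI at day 4, and at 3.64, 37.9 and 0.0791 at day 7. Myc, a driver of growth, was at 93.7, 98.5 and 7.40 at day 4. Klf4 was at 76.6, 116 and 37.8 at that day, against 20.4 in KI MEF. The labels give the KI cells the same inducible cassette, and the libraries labelled KI at days 4, 6 and 7 held Pou5f1 at 0.512 to 0.887 times and Sox2 at 0.225 to 0.751 times the higher of their KI values in MEF and at day 0. The table does not separate transgene from endogenous RNA.

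**Figure D1:**
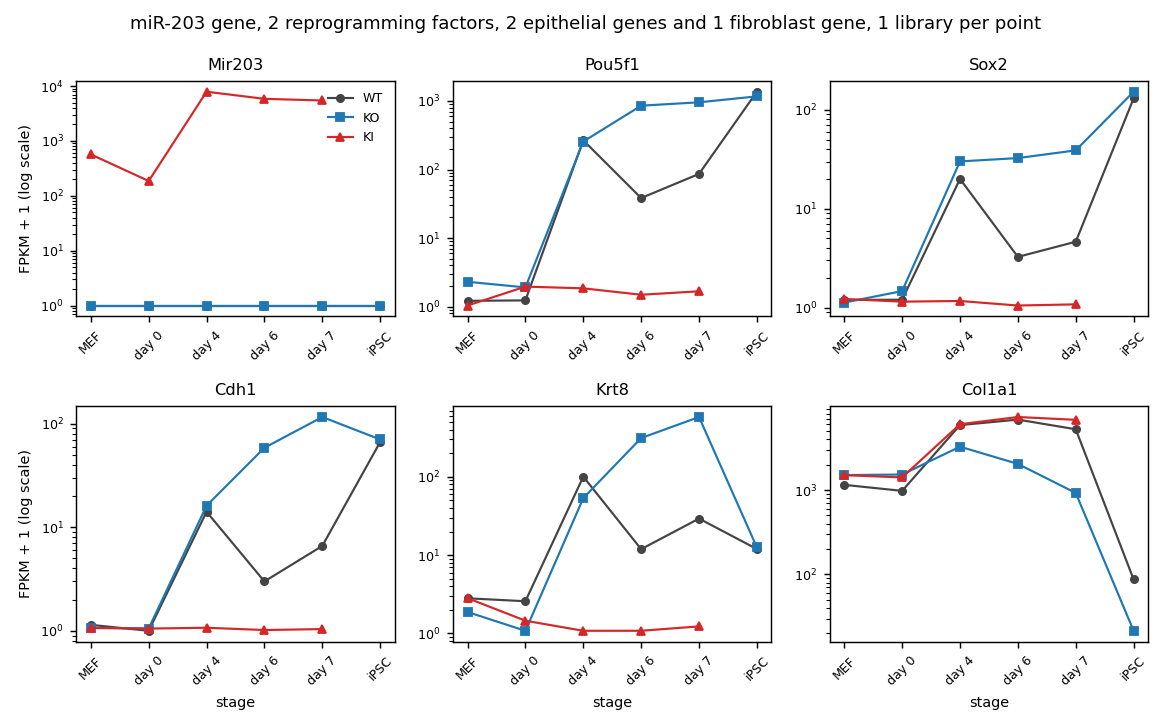
FPKM plus 1 (log axis) of Mir203, Pou5f1, Sox2, Cdh1, Krt8 and Col1a1 at the 6 stages, 1 point per library, with circles for WT, squares for KO and triangles for KI. For Mir203 the WT points lie under the KO points at 0, and for Pou5f1 and Sox2 the KI points stay near 0 at all 5 stages measured.

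Other libraries stood apart by RNA of the sex chromosomes and of macrophages. Xist, the RNA that silences an X chromosome in female cells, had an FPKM of 46.9 in WT MEF and 48.0 in WT day 4, against 1.42 in WT day 0 and 3.23 in WT day 7. The Y-linked gene Ddx3y was at 0.0179 in WT MEF, 2.74 in WT day 4 and 1.51 in WT iPSC, and between 14.5 and 20 in the other libraries. Lyz2, the lysozyme of macrophages, was at 60.4 in WT MEF and 2649 in WT day 7, at 18.4 and 1601 in KI, and at 8.21 and 12.3 in KO. C1qa, a complement subunit made by macrophages, was at 195 in WT, 55.5 in KI and 0.636 in KO at day 7.

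**Figure D2:**
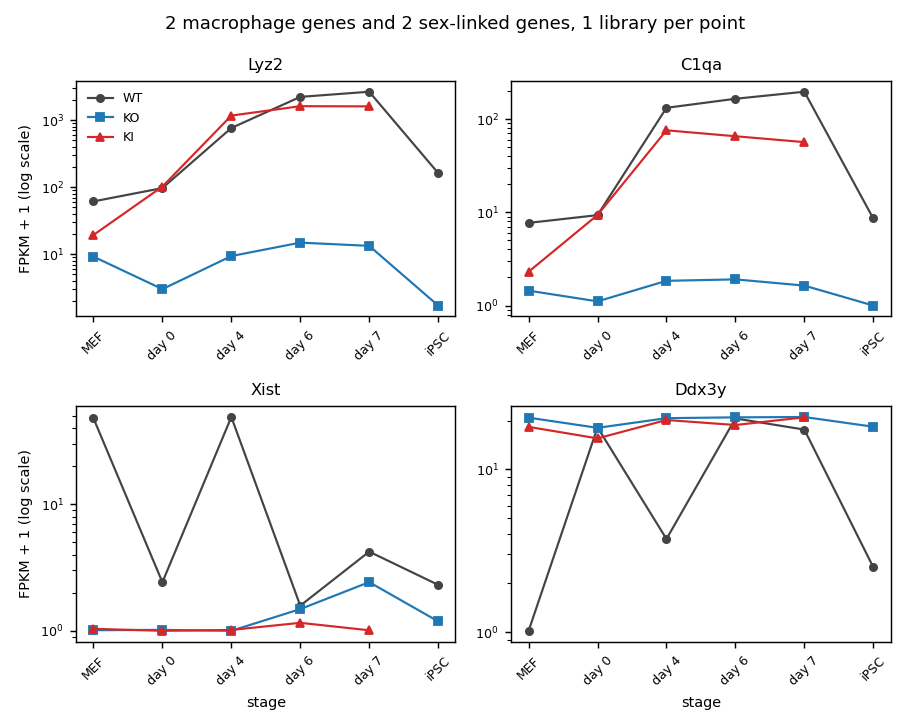
FPKM plus 1 (log axis) of Lyz2, C1qa, Xist and Ddx3y at the 6 stages, 1 point per library, with circles for WT, squares for KO and triangles for KI. Xist is high in WT MEF (46.9) and WT day 4 (48.0), and Lyz2 at day 7 is at 2649 in WT, 1601 in KI and 12.3 in KO.

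The step from MEF to day 0 asked what differed at the start of the time course. Txnip (ENSMUSG00000038393), an inhibitor of glucose uptake, rose by 3.18 ± 0.31 (log2, SE, 3 libraries per stage, adjusted p = 0.0034), and its relative Arrdc4 rose by 1.91 ± 0.26 (adjusted p = 0.039). The gap junction gene Gjb2 rose by 1.49 ± 0.21. Actc1, a muscle actin, fell by 2.49 ± 0.32, the imprinted growth-restraining RNA H19 fell by 2.30 ± 0.30, and the sialomucin gene Emcn fell by 1.55 ± 0.22. Among 21 imprinted genes 1 fell over all genes and 5 fell adjusted over the list alone, with a median of -0.56 and an adjusted p of 1.6e-08 by camera. That call was lost with an estimated correlation (adjusted p = 0.71). The 17 smooth muscle genes had a median of 0.43 (adjusted p = 5.8e-06, and adjusted p = 0.71 with an estimated correlation), and no member passed the test over all genes. In all, limma called 7 of 14240 genes, 4 higher and 3 lower, and 688 had an unadjusted p under 0.05. Without the WT, the KO or the KI libraries 11, 8 and 7 genes were called, each time with 1 of the 7 among them. The count was 3 without the late KI libraries or with quantile normalization, 4 with a pseudocount of 0.1, 2 with a filter at 5 and 15 with no filter.

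The step from day 0 to day 4 was compared over the 3 genotypes, and the genes named here changed in the same direction in each. In KI at day 4 Pou5f1 was at 0.887, Sox2 at 0.751, Myc at 0.152 and Klf4 at 1.46 times the higher early KI value. The changes were therefore not limited to cells in which Pou5f1 and Sox2 RNA rose. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), an acute-phase protein, rose by 10.49 ± 0.65 (log2, SE, 3 libraries per stage, adjusted p = 4e-06). The acute-phase gene Serpina3n rose by 8.46 ± 0.57, complement C3 by 7.26 ± 0.35, the iron-binding defence protein Lcn2 by 6.54 ± 0.27, and the matrix proteoglycan Lum by 7.20 ± 0.51. Also among the 10 largest increases were Reg3g, Agtr2, Steap4, Reg1 and Dpt. The YAP and TGF-beta responsive genes Ankrd1 and Ctgf fell by 5.52 ± 0.34 (adjusted p = 4e-06) and 5.07 ± 0.38, and the smooth muscle genes Cnn1 and Tagln by 5.03 ± 0.45 and 4.53 ± 0.50. Ptgs2, Cck, Sprr2k, Lce1h and Hbegf were also among the 10 largest decreases.

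From day 0 to day 4, 15 of 17 smooth muscle genes fell and 1, Tgfbi, rose (15 and 1 adjusted over the list alone), with a median of -2.58 and an adjusted p of 1e-11 by camera. Of 22 interferon response genes 17 rose, among them Zbp1 (4.15 ± 0.44) and Isg15 (2.92 ± 0.57), and Ifit2 fell (-0.77 ± 0.23). Adjusted over the list alone 21 rose and 1 fell, with a median of 1.80 and an adjusted p of 3.6e-09. Of 20 inflammatory genes 14 rose, Cxcl5 by 6.23, and 2 fell, Ptgs2 and Csf1 (15 and 3 adjusted over the list alone), with a median of 2.09 and an adjusted p of 3.3e-07. For these 3 lists the adjusted p was 0.71 with an estimated correlation. Of 15 macrophage genes 2 rose (6 adjusted over the list alone, median 2.08, adjusted p = 0.0012, and adjusted p = 0.89 with an estimated correlation), while Lyz2 at day 4 was at 762 in WT, 1167 in KI and 8.39 in KO. Of 37 fibroblast and mesenchymal genes 16 rose, such as Dcn (5.68), Col3a1 (5.36) and Pdgfra (3.18), and 9 fell, such as Fn1 (-1.48) and Cdh2 (-1.50), and the list passed no test (16 and 10 adjusted over the list alone, adjusted p = 0.18). Among imprinted genes H19 (4.16), Mest (4.13) and Cdkn1c (2.98) were among 8 that rose, and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.073). Glycolysis lost 4 of 15 genes (4 adjusted over the list alone, median -0.93, adjusted p = 0.0073, and adjusted p = 0.89 with an estimated correlation). The 33 cell cycle genes had a median of -0.63, with 1 member falling over all genes and 0 adjusted over the list alone (adjusted p = 0.0045, and adjusted p = 0.92 with an estimated correlation).

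By limma 3182 of 14240 genes changed between day 0 and day 4, 1756 higher and 1426 lower. Quantile normalization turned the split to 1246 higher and 1777 lower. The count was 871 without the WT libraries, 1005 without the KI libraries and 1899 without the KI libraries of days 4, 6 and 7 alone. The 4 reprogramming factors had a median of 2.18 with 1 rising over all genes and 3 adjusted over the list alone (adjusted p = 0.18), and the KI library of day 4 held Pou5f1 at 0.851.

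From day 4 to day 7 list means moved differently in the 3 genotypes, and few genes passed a test over all 3. The mean of the epithelial list (log2 of FPKM + 1) went from 1.52 to 5.48 in KO, 1.73 to 1.95 in WT and 0.489 to 0.459 in KI, and that of the pluripotency list from 1.11 to 3.63 in KO, 1.28 to 1.61 in WT and 0.604 to 0.535 in KI. Over the 3 genotypes together Slpi, an inhibitor of leukocyte proteases, rose by 2.43 ± 0.31 (log2, SE, 3 libraries per stage, adjusted p = 0.039), and the chemokine gene Cxcl16 rose by 0.97 ± 0.12 (adjusted p = 0.038). The 37 pluripotency genes had a median of 0.76 and an adjusted p of 5e-12 by camera, and the 26 epithelial genes a median of 1.32 and an adjusted p of 8.2e-09. The pluripotency median was 1.37 with a pseudocount of 0.1. Both calls were lost with an estimated correlation (adjusted p = 0.75), and over all genes no member of either list passed (1 and 0 adjusted over the list alone). The 20 inflammatory genes had a median of 0.53 (5 rose adjusted over the list alone, adjusted p = 2.2e-07, and adjusted p = 0.71 with an estimated correlation), and so had the 15 macrophage genes (0 adjusted over the list alone, adjusted p = 0.0058, and adjusted p = 0.89 with an estimated correlation). In all, limma called 3 of 14240 genes, 2 higher and 1 lower, with 1025 at an unadjusted p under 0.05. The count was 12 without the WT libraries, 10 without the KO libraries, 5 with no filter and 1 with a filter at 5, with a pseudocount of 0.1, with quantile normalization or without genotype in the fit.

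Day 7 was also set against MEF. Saa3 rose by 11.09 ± 0.65 (log2, SE, 3 libraries per stage, adjusted p = 3e-06), the neutrophil chemokine Cxcl5 by 8.28 ± 0.59, C3 by 7.95 ± 0.35 and Lcn2 by 7.36 ± 0.27, with Reg3g, Serpina3n, Ccl11, Ccl8, Steap4 and Lum among the 10 largest. Acta2, the smooth muscle actin, fell by 4.00 ± 0.56, and Hmga2, a chromatin protein of growing mesenchyme, fell by 4.12 ± 0.62 (adjusted p = 0.001). Cnn1, Ankrd1, Tagln, Des, Ctgf, Ptgs2 and Mcam were also among the 10 largest decreases. Dnmt3l, a cofactor of DNA methylation in germ and stem cells, rose by 2.87 ± 0.22 (adjusted p = 1.6e-05), and Tet1, which oxidises methylated DNA, by 1.22 ± 0.38 (adjusted p = 0.04). Both genes are members of the DNA methylation and the pluripotency list. In the DNA methylation list they were the 2 of 11 that rose (2 adjusted over the list alone), with a median of -0.12, a mean of 0.38 and an upward direction by camera (adjusted p = 0.49).

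Against MEF, inflammatory genes at day 7 rose in 16 of 20 and fell in 2 (16 and 2 adjusted over the list alone, median 3.33, adjusted p = 5.1e-13). Interferon genes rose in 18 of 22, Xaf1 by 3.60, and fell in 1 (21 and 1 adjusted over the list alone, median 1.66, adjusted p = 3.1e-10). Macrophage genes rose in 12 of 15, Lyz2 by 4.11 ± 0.95 and Laptm5 by 4.14 (15 adjusted over the list alone, median 3.18, adjusted p = 1.7e-07), and Lyz2 stood at 12.3 in KO against 2649 in WT at day 7. Smooth muscle genes fell in 13 of 17 and rose in 1 (14 and 1 adjusted over the list alone, median -1.98, adjusted p = 1e-08). With an estimated correlation the adjusted p was 0.71 for each of these 4 lists. Glycolysis fell in 6 of 15, with Slc16a3 (-2.28), Eno1 (-1.87) and Ldha (-1.28) among them (7 adjusted over the list alone, adjusted p = 0.0063), and cell cycle genes fell in 3 of 33, Foxm1 by 1.40 (0 adjusted over the list alone, median -0.85, adjusted p = 7.9e-04). Pluripotency genes had a median of 1.28 with 2 rising (1 adjusted over the list alone, adjusted p = 2.4e-04). Epithelial and keratinocyte genes had medians of 1.67 and 2.58 with no member past the test (adjusted p = 0.0022 and 0.016), and HOX genes, which pattern the body axis, had a median of -0.39 with 1 of 29 rising and 5 falling (1 and 5 adjusted over the list alone, adjusted p = 0.033). For these 6 lists the adjusted p was 0.89 with an estimated correlation. Between MEF and day 7 list means (log2 of FPKM + 1) moved differently in the genotypes. Glycolysis went from 6.617 to 6.968 in KO, 6.571 to 5.277 in WT and 6.609 to 4.705 in KI. Cell cycle went from 4.88 to 5.394, 5.143 to 4.145 and 5.113 to 2.951 in that order. Epithelial genes rose from 0.87 to 5.481 in KO and 1.008 to 1.953 in WT but fell from 1.002 to 0.459 in KI. Pluripotency genes rose from 0.747 to 3.626 in KO and 0.718 to 1.605 in WT but fell from 0.734 to 0.535 in KI. The size of some medians rested on the pseudocount, and with 0.1 they were 2.54 for pluripotency, 2.93 for epithelial and 3.97 for keratinocyte genes, and also larger for interferon genes. Altogether limma called 3050 of 14240 genes, 1543 higher and 1507 lower, and after quantile normalization 1191 higher and 1812 lower. The count was 741 without the WT libraries, 834 without the KI libraries, 1541 without the KI libraries of days 4, 6 and 7 and 1942 without the WT libraries of MEF, day 4 and iPSC.

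**Figure D3:**
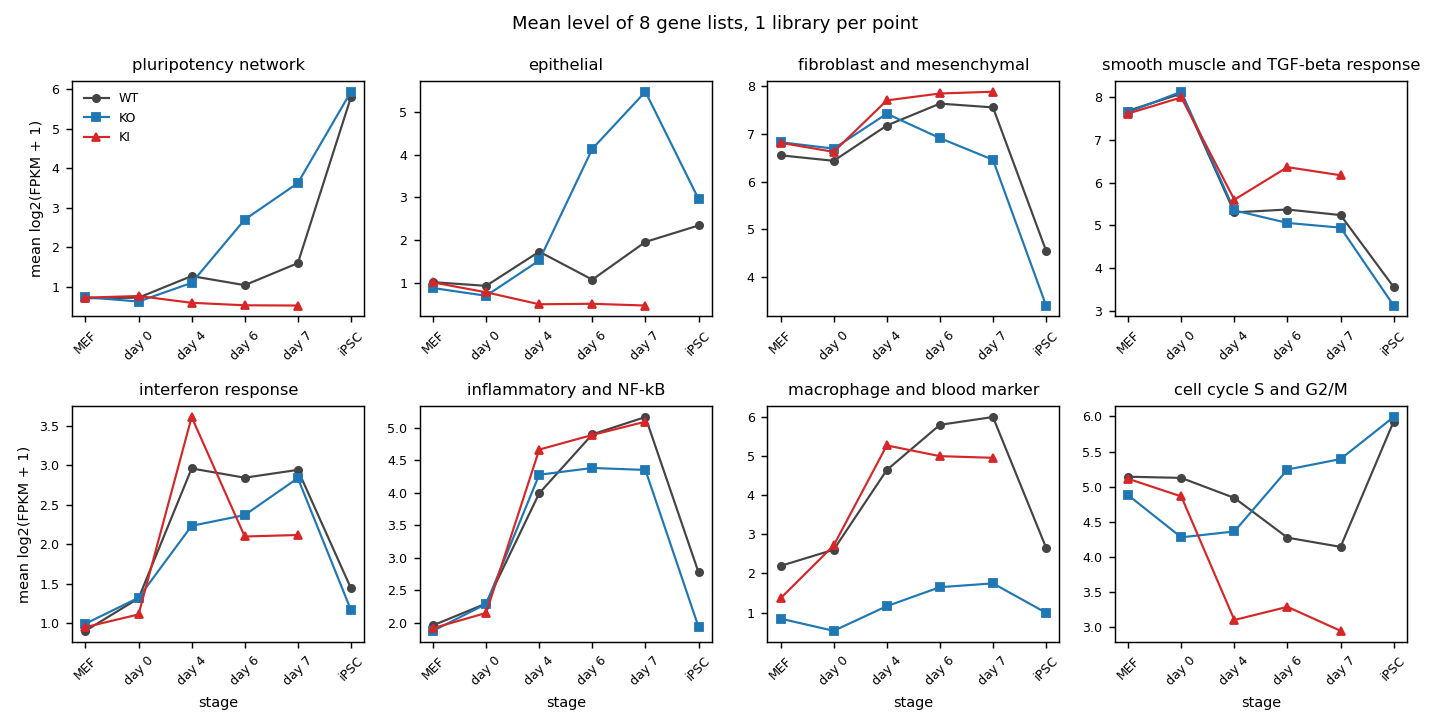
Mean log2 (FPKM + 1) of 8 gene lists fixed before the data were examined, at the 6 stages, 1 point per library, with circles for WT, squares for KO and triangles for KI. Macrophage genes are lower in KO than in WT at every stage, and pluripotency genes are highest in iPSC.

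Moving from day 7 to iPSC, the stem cell program rose and the mesenchymal one fell. Nr0b1, a nuclear receptor of pluripotent cells, rose by 5.67 ± 0.33 (log2, SE, 2 iPSC libraries against 3, adjusted p = 7e-07), Esrrb by 5.59 ± 0.51, Tcl1, a cofactor of AKT, by 6.10 ± 0.41, and Dppa5a by 5.61 ± 1.82 (adjusted p = 0.025). Rpl10l, Rbmxl2, Trap1a, Pla2g1b and Fmr1nb were further large increases. Cxcl5 fell by 9.30 ± 0.67 and the collagen gene Col3a1 fell by 7.67 ± 0.74, beside Reg3g, Serpina3n, Ptx3, Saa3, Ptn, Wisp2 and Ogn. Pluripotency genes rose in 34 of 37 (36 adjusted over the list alone, median 3.72, adjusted p = 5.1e-13), and fibroblast genes fell in 35 of 37, Col1a1 by 5.98 (35 adjusted over the list alone, median -3.09, adjusted p = 1e-15). HOX genes fell in 27 of 29, such as Hoxa10 (-2.43; 27 adjusted over the list alone, median -1.36, or -2.48 with a pseudocount of 0.1, adjusted p = 6.6e-08). Inflammatory genes fell in 16 of 20 (1 rose and 16 fell adjusted over the list alone, median -2.48, adjusted p = 2.2e-07), and smooth muscle genes fell in 12 of 17 and rose in 1 (12 and 1 adjusted over the list alone, adjusted p = 1e-04). For these 5 lists the adjusted p was 0.71 with an estimated correlation. Interferon genes fell in 14 of 22 (15 adjusted over the list alone, adjusted p = 5.7e-04), macrophage genes in 8 of 15 (11 adjusted over the list alone, adjusted p = 0.0093), and cell cycle genes rose in 15 of 33, Mcm2 by 2.83 and Mcm3 by 2.60 (11 adjusted over the list alone, median 1.51, adjusted p = 5.5e-04), each with an adjusted p of 0.89 with an estimated correlation. DNA methylation genes rose in 6 of 11, with Tet1 (3.57) and Dnmt3b (3.19), and Tet3 fell (-0.75; 9 and 1 adjusted over the list alone, adjusted p = 0.016). Imprinted genes rose in 2 of 21, Zdbf2 (3.14) and Snrpn (2.23), and fell in 10, Igf2 by 6.28 and H19 by 6.21 (3 and 11 adjusted over the list alone, adjusted p = 0.011). For the last 2 lists the adjusted p was 0.75 with an estimated correlation.

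This step held the largest count, 7082 of 14240 genes by limma, 3649 higher and 3433 lower. The majority depended on the processing, with 3347 higher and 3877 lower after upper-quartile scaling and 5161 and 3582 with no filter. It was 752 and 1615 without the WT libraries, 1919 and 2442 without the KI libraries, and 1544 and 2576 without the WT libraries of MEF, day 4 and iPSC. KI has no iPSC library, and the median of all genes was shifted by 0.114.

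The end points, iPSC and MEF, differed by the full pluripotency list. Dppa5a rose by 9.99 ± 1.82 (log2, SE, 2 iPSC libraries against 3, adjusted p = 0.0012), Pou5f1 by 8.33 ± 1.96 (adjusted p = 0.0057), Tdgf1, a co-receptor of Nodal, by 7.45 ± 1.04, and Utf1, Lefty2, Sept1, Esrrb, Rhox5 and Tcl1 were also among the largest. Acta2 fell by 7.99 ± 0.64, Tagln by 7.02 ± 0.57, the growth factor Igf2 by 6.89 ± 0.35 and the collagen crosslinker Lox by 6.15 ± 0.58, with Actg2, Myl9, Dlk1, Fbln5 and H19. All 37 pluripotency genes rose (37 adjusted over the list alone, median 5.17, adjusted p = 1.1e-16). Fibroblast genes fell in 32 of 37 and rose in 1 (32 and 1 adjusted over the list alone, median -2.89, adjusted p = 5.1e-13), smooth muscle genes fell in 15 of 17 (16 adjusted over the list alone, median -4.33, adjusted p = 7.7e-11), HOX genes in 26 of 29, Hoxb9 by 3.10 (27 adjusted over the list alone, median -1.80, larger with a pseudocount of 0.1, adjusted p = 3.9e-10), and imprinted genes in 11 of 21, with 3 rising (11 and 3 adjusted over the list alone, adjusted p = 0.0059). The adjusted p for all of these was 0.71 with an estimated correlation. DNA methylation genes rose in 4 of 11, Dnmt3l by 6.61 and Dnmt3b by 4.39, and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.016, and adjusted p = 0.75 with an estimated correlation). Epithelial genes rose in 7 of 26, Cdh1, the adhesion protein of epithelia, by 5.15 ± 1.40 and Epcam by 4.22 ± 1.36, and fell in 3, among them Krt19 (-4.20; 7 and 3 adjusted over the list alone, adjusted p = 0.18). Called by limma were 5955 of 14240 genes, 2913 higher and 3042 lower, with 2789 without the WT libraries, 3896 without the WT libraries of MEF, day 4 and iPSC, and a median of all genes of 0.117.

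Across the 5 stages before iPSC, the question for KO was what differed from WT. With 1 library per genotype and stage, the p values measure how constant a difference is over stages, not the spread between cultures or embryos. An effect of miR-203 and a difference between the series of libraries are thus not told apart. The largest decreases in KO held 6 members of the macrophage list, Lyz2, C1qa, C1qb, C1qc, Tyrobp and Fcer1g. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321) fell by 5.79 ± 0.76 (log2, SE, 5 stage-matched pairs, adjusted p = 0.019), C1qb fell by 5.18 ± 0.65 and Tyrobp fell by 5.13 ± 0.70, and C1qa, C1qc, Alox5ap, Fcer1g, Ctss, Apoe (-3.93 ± 0.49) and Pf4 completed the 10. Nr2f1, a nuclear receptor of neural crest and mesenchyme, rose by 1.49 ± 0.17 (adjusted p = 0.015), Ahr, the dioxin receptor, by 1.38 ± 0.23 (adjusted p = 0.045) and Mab21l2 by 1.09 ± 0.11 (adjusted p = 0.007), with Jmjd7, Masp1, Ttc9, Ly6c1, Cd80, Spg11 and Ypel2. Other genes share 63.1% of the 31-base stretches of Jmjd7, 46.8% of those of Ly6c1 and 32.8% of those of Lyz2, so the reads of these 3 are less certain. Of 15 macrophage genes 6 fell over all genes and 15 adjusted over the list alone (median -3.49, adjusted p = 4.1e-29, and adjusted p = 0.32 with an estimated correlation). Of 29 HOX genes Hoxc10 fell (-1.31 ± 0.17, adjusted p = 0.017), and 1 rose and 10 fell adjusted over the list alone (median -0.33, adjusted p = 4.7e-09, and adjusted p = 0.70 with an estimated correlation). The 21 imprinted genes had a median of -0.43 (4 fell adjusted over the list alone, adjusted p = 2.7e-06, and adjusted p = 0.62 with an estimated correlation). Pluripotency, epithelial and keratinocyte genes had medians of 0.91, 1.35 and 1.59 with no member past the test over all genes (0, 1 and 0 adjusted over the list alone, the 1 falling). Their adjusted p by camera was 0.007, 0.0031 and 0.015, and with an estimated correlation the adjusted p was 0.82, 0.81 and 0.81. The 37 fibroblast genes had a median of -0.27 (adjusted p = 4.9e-04, and adjusted p = 0.81 with an estimated correlation). Limma called 47 of 13837 genes, 22 higher and 25 lower, with a median of all genes of 0.109. With only KO and WT in the fit limma called 0 genes, with 1180 at an unadjusted p under 0.05, and the count was 6 without the stage term, 26 with a filter at 5, 27 with no filter and 160 (43 higher, 117 lower) with a pseudocount of 0.1. It was 86 without MEF, 9 without day 4 and 1 without day 0, without day 6 or without day 7, and the WT libraries of MEF and day 4 are those with Xist. Without both of these stages it was 5, and 1 macrophage gene was called, while all 15 stayed lower with a median of -4.11.

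For KI the same question was asked, and the p values have the same limit. Lower in KI were Fbxo44 (ENSMUSG00000029001, chromosome 4, 148152800 to 148160482), a subunit of a ubiquitin ligase, which fell by 1.77 ± 0.19 (log2, SE, 5 stage-matched pairs, adjusted p = 0.0014). Ppp1r3e, which targets a phosphatase to glycogen, fell by 1.69 ± 0.17, and Trnp1, Tceanc2 and Stxbp2 (-1.39 ± 0.23) fell as well. Larger decreases in Rps3a3, Tpm3-rs7, Rps3a2 and Eif3j2 belong to near-identical gene copies, whose reads cannot be placed with certainty. BC002163, which was higher in KI, is uncertain too, since 81.0% of its 31-base stretches also occur in Ndufs5. Ndufs5, a subunit of mitochondrial complex I, was lower in KI (-1.40 ± 0.12). It shares 26.5% of its stretches with BC002163, so its reads are less certain, but most of its sequence is its own. Higher in KI were Cd59a, an inhibitor of complement (1.07 ± 0.17, adjusted p = 0.032), the mechanosensitive channel Piezo2 (0.98 ± 0.17, adjusted p = 0.039), Spg11 (0.94 ± 0.13) and Hebp1 (0.89 ± 0.12), with AA465934, Galnt18, Tmem200a, Rerg and Rnf167. The 33 cell cycle genes had a median of -0.85 (adjusted p = 1.7e-07), the 37 fibroblast genes 0.34 (adjusted p = 3.3e-08) and the 10 keratinocyte genes -1.75 (-3.26 with a pseudocount of 0.1, adjusted p = 0.013), each with an adjusted p of 0.81 with an estimated correlation. The 17 smooth muscle genes had a median of 0.26 (adjusted p = 1.2e-05, and adjusted p = 0.76 with an estimated correlation). Over all genes and adjusted over the list alone no member of these 4 lists passed. Limma called 55 of 13837 genes, 26 higher and 29 lower, with a median of all genes of -0.102, and the count was 28 with a filter at 5, 30 without day 0, 32 without day 6 and 22 without both MEF and day 4.

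Whether the difference from WT changed between early and late stages was tested by an interaction. In KO the chemokine gene Ccl6 (-5.16 ± 0.52, log2, SE, 5 libraries per genotype, adjusted p = 0.021), Wfdc17 (-4.46 ± 0.55), the complement factor properdin gene Cfp (-3.90 ± 0.48) and the scavenger receptor gene Stab1 (-2.96 ± 0.31) fell further in the late stages, as did Rarres2 (-2.70 ± 0.28) and Il11ra1 (-1.78 ± 0.18). The osteocalcin gene Bglap2 rose by 3.08 ± 0.37 (adjusted p = 0.044), but 95.2% of its 31-base stretches also occur in other genes, and 57.7% of those of Il11ra1. Macrophage genes had a median of -2.80 (12 of 15 fell adjusted over the list alone, adjusted p = 7.2e-10, and adjusted p = 0.70 with an estimated correlation), and the fibroblast list -0.71 (4 fell adjusted over the list alone, adjusted p = 3.3e-08). Epithelial genes had a median of 2.56 and cell cycle genes a mean of 1.13 (adjusted p = 7.3e-04 and 1.8e-06), and for these and the fibroblast list the adjusted p was 0.81 with an estimated correlation. In KI the 4 reprogramming factors had a median of -2.36, and all 4 fell adjusted over the list alone (adjusted p = 3e-04, and adjusted p = 0.70 with an estimated correlation). Cell cycle genes had a median of -1.17 (adjusted p = 2.9e-10, and adjusted p = 0.81 with an estimated correlation) and smooth muscle genes 0.70 (3 rose adjusted over the list alone, adjusted p = 4.8e-09, and adjusted p = 0.63 with an estimated correlation). Limma called 11 of 13837 genes in KO, 4 higher and 7 lower, and 10 in KI, 5 and 5. The fit counts day 4 as late, and any change of the difference between days 4, 6 and 7 adds to its spread. The KO count was 17 with no filter, 6607 without day 4, 58 without MEF, 47 without day 0, 4 without day 6, 6 without day 7 and 4195 without both MEF and day 4. The KI count was 164 without day 4, 56 without MEF, 60 without day 0, 3 without day 6 and 107 without both MEF and day 4. The medians of all genes were 0.163 in KO and -0.165 in KI.

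Pairs of single libraries showed where the genotypes parted, as values without a test. At day 7 the epithelial genes Cdh1 and Krt8 had an FPKM of 115 and 579 in KO, 5.59 and 28.3 in WT, and 0.0396 and 0.231 in KI. Col1a1, the main fibroblast collagen, was at 921 in KO, 5243 in WT and 6781 in KI. In KO at day 7, 25 of 26 epithelial genes were at least 2-fold higher than in WT (median 3.80), as were 31 of 37 pluripotency genes (median 2.05), 10 of 10 keratinocyte genes (median 3.73) and 15 of 15 glycolysis genes (median 1.43). There 23 of 37 fibroblast genes (median -1.31) and 15 of 15 macrophage genes (median -5.67) were at least 2-fold lower, as were 12 of 29 HOX genes (median -0.87). At day 4, before that divergence, the medians in KO were -0.06 for epithelial, -0.12 for pluripotency and -3.92 for macrophage genes. The 4 reprogramming factors had medians in KO of 0.33 at day 4, 3.04 at day 6 and 2.82 at day 7. Their mean (log2 of FPKM + 1) at days 4, 6 and 7 was 6.306, 4.015 and 4.536 in WT and 6.604, 7.100 and 7.244 in KO. The gap thus opened more by lower values in WT than by higher ones in KO, and WT day 4 is a library with Xist. All 4 factors were at least 2-fold higher in KO than in WT at days 6 and 7. The KO and WT libraries of those days thus differed in factor RNA too, and whether that accounts for the other differences was not tested. In iPSC 20 of 37 fibroblast genes (median -1.09) and 9 of 15 macrophage genes (median -1.95) were at least 2-fold lower in KO, and pluripotency genes had a median of 0.24.

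The KI and WT libraries differed in the most genes at day 4, where the WT library had Xist at 48.0 and Ddx3y at 2.74. Across genes, the KI library of day 4 had an r of 0.834 with WT day 4, 0.903 with WT day 6 and 0.892 with WT day 7. At day 4, 28 of 33 cell cycle genes (median -1.77), 18 of 19 ribosome genes (median -1.51), 9 of 10 keratinocyte genes (median -3.49) and 11 of 26 epithelial genes (median -0.90) were at least 2-fold lower than in WT, and 10 of 20 inflammatory genes (median 0.96) and 8 of 22 interferon genes (median 0.76) at least 2-fold higher. At days 6 and 7 interferon genes had medians of -0.77 and -0.81, with 9 and 6 at least 2-fold lower and 0 higher. Macrophage genes had a median of 0.86 at day 4, -0.80 at day 6 and -1.10 at day 7. Acta2 was at 619 in KI and 117 in WT at day 7, and smooth muscle genes had medians of 1.13 at day 6 and 0.85 at day 7. At day 7, 21 of 33 cell cycle genes (median -1.24) and 16 of 26 epithelial genes (median -1.27) were at least 2-fold lower. Medians of weakly expressed lists were larger with a pseudocount of 0.1, at -1.99 for epithelial and -5.32 for keratinocyte genes at day 4 and -3.04 for epithelial genes at day 7.

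**Figure D4:**
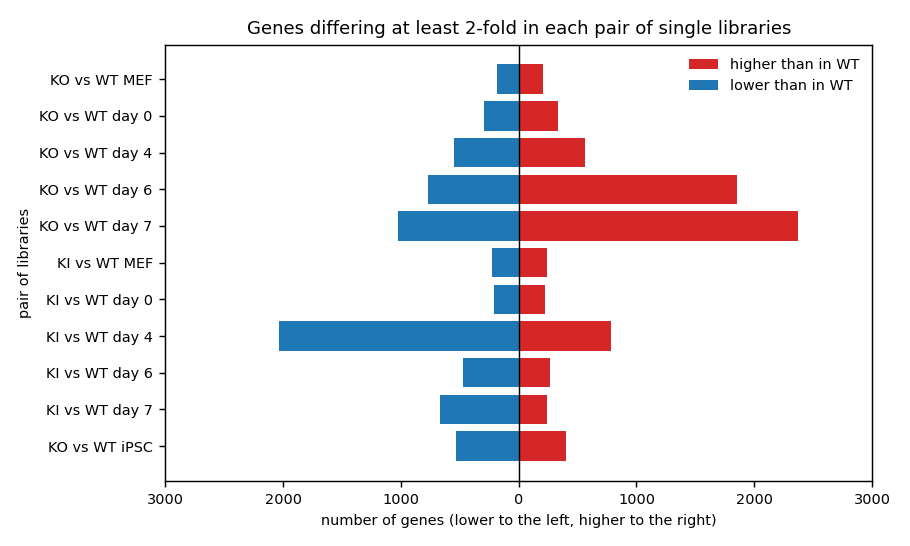
Number of genes at least 2-fold higher (bars to the right) or lower (bars to the left) than in WT for each pair of libraries, among genes with an FPKM of at least 5 in 1 of them. KO at day 7 has 2370 higher and 1024 lower, and KI at day 4 has 783 higher and 2035 lower.

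The counts of genes at least 2-fold apart followed these groups. KO differed from WT in 398 genes in MEF, 634 at day 0, 1107 at day 4, 2618 at day 6, 3394 at day 7 and 935 in iPSC. KI differed in 468, 436, 2818, 745 and 907 genes from MEF to day 7. At day 7 the KO split was 2370 higher and 1024 lower, or 1500 and 1451 after rescaling to a common upper quartile, and at day 6 it was 1850 and 768, or 1262 and 1110. In KI at day 4 it was 783 and 2035, or 1292 and 1375 after that rescaling. Days 6 and 7 of 1 genotype differed in 334 genes in WT, 540 in KO and 298 in KI.

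The direct trace of a microRNA was sought in genes with miR-203 sites. In KI the 2048 genes with a site lay below the 9883 without by a matched difference of -0.0365 (log2) at day 6, -0.0234 at day 7 and -0.0139 at day 0. Of 209 control 7-mers 3, 8 and 11 gave a difference as low. All 3 values rested on the matching, since the unmatched differences were -0.015 at day 6, 0.043 at day 7 and -0.002 at day 0. The value at day 7 also rested on the site type. There the matched difference was -0.0011 for sites matching bases 2 to 7 before an A. At day 4 it was 0.0404 (48.3% of controls lower) and in MEF -0.0046 (77 as low), and averaged over days 4, 6 and 7 it was -0.0001 (27 as low) and over the 5 stages -0.0054 (14 as low). In KO the difference was 0.0740 at day 4 (190 controls as low), -0.0211 at day 7 (55 as low) and 0.0025 over the 5 stages (66 as low). Among 21 published miR-203 targets tested no gene passed over all genes in KI or KO. Their median was -0.12 in KI (2 fell adjusted over the list alone, adjusted p = 0.75) and 0.04 in KO against a downward direction by camera (0 adjusted over the list alone, adjusted p = 0.51). Between stages these targets fell in 8 and rose in 3 from day 0 to day 4 (8 and 3 adjusted over the list alone, adjusted p = 0.054).

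The KO and KI differences share the WT libraries, so their resemblance was set against simulated groups without change. Across genes, which are not independent replicates, r was 0.07 against a simulated 0.49, and the covariance was 0.021 against 0.078. Spg11, a gene of lysosome function, was the 1 gene called higher in both, and 3 were called lower in both. Independent lists would give 0.041 and 0.052, and the simulations gave at most 1. Of the 3 lower genes, Eif3j2 shares 94.9% of its 31-base stretches with other genes, and the rest are a pseudogene and a predicted gene by their symbols. The simulations held no changed genes, and independent lists do not share WT libraries. Neither can therefore tell whether the overlap exceeds what shared WT libraries give among called genes. With separate WT stages for KO and KI, r was -0.225 in one arrangement and -0.039 in the other.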

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

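The tests of the patterns below were chosen only after the results were seen, except the nearness of day 4 values and the share of sex chromosome genes, which were set before their own result was known.

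The difference from WT changed between early and late stages in 11 genes in KO and in 10 genes in KI, each by an interaction term in limma. Larger in the late stages of KO was the difference in Bglap2 (3.08) and, with an unstable value because the RNA is short, in Rny3 (5.27). Lower in the late stages of KO were Ccl6 (-5.16), Wfdc17 (-4.46), Cfp (-3.90), Stab1 (-2.96), Rarres2 (-2.70) and Il11ra1 (-1.78). For KO 69 of 100 splits of the libraries called as many genes and the highest other split called 1629. For KI it was 71 of 100, with 89 as the highest other. Chance is not excluded for either count, and counts so far above the real ones point to a structure of the samples. Exchanging WT and KO at day 4 alone called 2002 genes for KO. No gene of the KI interaction passed the rule for named genes.

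For the comparisons over 5 stages the splits ignore the matching by stage. The libraries of 1 genotype are not replicates, so the splits cannot exclude chance differences between cultures or embryos. The real KI split called 55 genes and the highest other split 1, so that 1 of 100 splits, the real one, called as many. The real KO split called 47 and 2 of 100 splits called as many, the highest other with 120. That other split exchanged the KO library of MEF with the WT library of day 4, which points to a structure of the samples. Exchanging the genotypes within stages, which keeps the matching, gives 16 arrangements, too few for a share under 0.05, with a highest other of 1 beside the real 47 in KO and of 1 beside the real 55 in KI. The KO count was also 0 with only KO and WT in the fit, with 1180 at an unadjusted p under 0.05 by limma, and 1 without day 0, without day 6 or without day 7. Between stages the splits are too few for a share under 0.05, since there are 10. The real counts of 7, 3182, 3 and 3050 for day 0 against MEF, day 4 against day 0, day 7 against day 4 and day 7 against MEF stand beside a highest other of 1, 3, 2 and 1, and in each 1 split, the real one, called as many.

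The KI libraries of days 4, 6 and 7 lacked Pou5f1, Sox2 and epithelial RNA. An absence of doxycycline is argued against by Mir203, which by the labels it induces and which was at least 9.61 times its highest early KI value in these libraries. Dilution by macrophage RNA is argued against by the fibroblast list, whose median was at least 0.25 above WT at each of the 3 days. Whether the OSKM factors were not induced in these cultures cannot be told apart from an action of miR-203 on the cells or on the factor RNA, the biological difference that the design names, which was not tested. The highest ratio of any of the 4 factors to its early KI value, 1.46 for Klf4 at day 4, is part of the pattern and decides neither.

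Macrophage RNA was low in the KO libraries. Scaling between libraries is argued against, since the median of the list was -3.52 after upper-quartile rescaling and -3.61 after quantile normalization. At day 7, 15 of 15 tested members, Lyz2 and C1qa among them, were at least 2-fold lower in KO, and 4 of 17 members reached an FPKM of 5 in KO against 15 in WT. These values are the pattern itself, so they do not decide whether the KO cultures held few macrophages or whether such cells expressed less. The design holds 1 KO series, so loss of miR-203 and a difference between cultures or embryos stay open and untested.

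The WT library of day 4 stood apart, and the late minus early counts rested on day 4, with 6607 genes in KO without it against 11. Day 4 was grouped with days 6 and 7, though the epithelial median in KO against WT was -0.06, 3.59 and 3.80 at days 4, 6 and 7. Such change within the late stages enters the spread of the fit and lowers its count. The 2 counts therefore do not show by themselves that the WT library of day 4 is at fault. A single WT culture of 1 sex through all stages is argued against by Ddx3y, whose highest WT value before iPSC was 1090 times its lowest. For an exchange of the WT and KO libraries of day 4, 5 of 9 genes called without day 4 lay nearer the KO mean in WT day 4, which falls between the bounds set beforehand, and 2 of 9 lay nearer the WT mean in KO day 4. The macrophage list argues against that exchange, with 15 of 15 members at least 2-fold lower in KO at day 4. Genes on X and Y made up 3.05% of 6558 called genes and 3.13% of 13581 tested. Of 425 tested genes on X and Y 200 were called. So few genes could not have made up most of the calls in any case, so the share decides nothing on sex as a source. It also does not cover effects of sex on other chromosomes. Different embryos or cultures and different rates of reprogramming stay open.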

How the results depend on the processing

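The alternatives without the KI libraries of days 4, 6 and 7, without the WT libraries of MEF, day 4 and iPSC, and without both MEF and day 4 were chosen after the data were seen, and the others before. No named gene and no list called by camera changed direction under the alternatives run. The majority of the genes called by limma did turn to the other direction in 35 of 124 recomputed counts, such as day 4 against day 0 (1246 higher, 1777 lower) and day 7 against MEF (1191 and 1812) with quantile normalization and iPSC against MEF (4657 and 3213) with no filter. Values without a call near 0 did change sign in places, such as the difference for miR-203 sites in KO over the late days (0.0068) and over 5 stages (0.0025), which both fell under 0 with 8-base sites. Of the counts and values recomputed, 161 stayed near their reported value and 68 moved. Named genes kept their call in 1326 recomputations and lost it in 373, list tests kept it in 91 and lost it in 95, and list medians in pairs stayed in 182 and moved in 110. Where not stated otherwise the cause was not tested.

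A pseudocount of 0.1 raised the size of several medians of weakly expressed lists, such as HOX genes for iPSC against day 7 (-1.36 to -2.48) and keratinocyte genes in KI (-1.75 to -3.26). It gave 4 genes for day 0 against MEF, 1 for day 7 against day 4 and 160 for KO against WT. No filter gave 15, 5 and 27 for these, and 17 for KO late minus early. A filter at 5 gave 2, 1 and 26, and 28 for KI against WT. Quantile normalization gave 3 for day 0 against MEF and 1 for day 7 against day 4, as did the fit without genotype for the latter. KO against WT had 6 genes without the stage term and 0 by limma with only the 2 genotypes compared (1180 at an unadjusted p under 0.05). An FPKM of 1 or more raised the KI pair at day 7 to 1391 genes, since more genes were compared. An estimated correlation left 0 of 93 list calls.

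Leaving out 1 genotype, which leaves fewer libraries per stage, gave 7 to 11 genes for day 0 against MEF, 871 to 3274 for day 4 against day 0, 3 to 12 for day 7 against day 4, 741 to 4402 for day 7 against MEF, 2367 to 6934 for iPSC against day 7 and 2789 to 4751 for iPSC against MEF. Where that left 1 iPSC library, it is assumed to vary like the other groups. Leaving out 1 stage gave 1 to 86 for KO against WT, lowest without day 0, day 6 or day 7 and highest without MEF, and 30 to 42 for KI against WT. It gave 4 to 6607 for KO late minus early and 3 to 164 for KI late minus early, in both lowest without day 6 and highest without day 4. Without the KI libraries of days 4, 6 and 7 there were 3 genes for day 0 against MEF, 1899 for day 4 against day 0 and 1541 for day 7 against MEF. Without the WT libraries of MEF, day 4 and iPSC there were 1942 for day 7 against MEF, 4120 for iPSC against day 7 and 3896 for iPSC against MEF. Without MEF and day 4 there were 5 for KO against WT, with 1 macrophage gene, 22 for KI against WT, 4195 for KO late minus early and 107 for KI late minus early.

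For miR-203 sites, 8-base sites gave matched differences in KO of 0.0427 at day 4, -0.0538 at day 6, -0.0748 at day 7, -0.0285 over the 3 late days and -0.0136 over 5 stages. In KI they gave -0.0751 at day 6, -0.0574 at day 7, -0.0418 over the late days (-0.0001 with 7-base sites) and -0.0303 over 5 stages. Sites matching bases 2 to 7 before an A gave 0.0710 at day 4, -0.0011 at day 7 and -0.0019 over MEF and day 0 in KI, and a filter at 5 gave -0.0118 in KI MEF. The read depth behind the FPKM is not given in the sources used here, so no limit from it was computed.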

Other observations

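The comparison of sites in genes higher in KI was chosen only after the result for the lower genes was seen.

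Trophoblast genes, markers of the placental lineage, were at least 2-fold higher in KO than in WT for 7 of 7 members at day 6 (median 2.66, or 4.44 with a pseudocount of 0.1) and 6 of 7 at day 7 (median 3.45). In KI 4 of 7 trophoblast genes were at least 2-fold lower than in WT at day 7 (median -1.25, or -3.85 with a pseudocount of 0.1). Markers of some other lineages were higher in KO too, with medians at days 6 and 7 of 1.73 and 1.68 for 6 endothelial genes, 1.58 and 1.66 for 6 neural genes and 1.68 and 2.59 for 4 genes of primed cells and early germ layers, the last 3.01 and 4.06 with a pseudocount of 0.1. The 7 chondrocyte and bone genes were not, with medians of -0.23 and 0.06. Of 9 extraembryonic endoderm genes 5 were at least 2-fold lower and 1 higher in KO at day 7 (median -1.44). Moving from day 7 to iPSC, genes of oxidative phosphorylation rose in 10 of 18 (10 adjusted over the list alone, median 0.82, adjusted p = 0.0047) and ribosome genes in 7 of 19 (7 adjusted over the list alone, median 0.94, adjusted p = 0.0058), each with an adjusted p of 0.89 with an estimated correlation. Genes of the p53 response had a median of 0.33 in KO over 5 stages (3 rose adjusted over the list alone, adjusted p = 6.7e-04, and adjusted p = 0.62 with an estimated correlation).

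A hypothesis set before its test was that genes lower in KI over 5 stages carry miR-203 sites more often. Of 20 such genes with a searched untranslated region 7 had a site, which is 35.0% (95% exact interval 15.4% to 59.2%) against 17.2% of all genes searched (one-sided exact hypergeometric p = 0.0427). Among the genes higher in KI 1 of 10 had a site. The lower genes had longer untranslated regions, with a median of 1365 bases against 1173 in all searched genes and 724 in the higher ones, and the test was not matched on length. Direct action of miR-203 on these genes may account for part of the group, but 1 KI series and so few genes leave it a hypothesis. The fit sought a difference held over 5 stages, and all 55 called genes had the same sign in all 5. Mir203, whose mature form was not measured, went in KI from 185 at day 0 to 7903 at day 4. None of the genes named as lower in KI was called in the KI comparison of late with early stages. In simulated data that comparison recovered 9% and 50% of changes of 1 and 2 (log2) in KI. It therefore cannot exclude that the differences follow Mir203.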
